A study of Rattus norvegicus with 40 samples.

How the data were processed

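Total RNA from adrenal glands of adult Sprague Dawley rats was extracted with a Qiagen column kit and sequenced on an Illumina instrument with a paired-end cluster kit, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation, the strand setting and any filter on reads are not given in the sources used here. The authors deposited 1 table per library with FPKM values for 32545 genes, and 9505 of these genes were at 0 in every library.

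The deposited FPKM values were tested for whole reads. In each library the value of a gene is a whole multiple of what 1 read is worth for a gene of that length, and the library scales and gene lengths that make the values whole were solved from the files, taking the shortest length that did so. For the 20717 genes with a value in at least 3 libraries, 100.0% of 680244 values above 0 lay within 0.05 of a whole read. Another 2323 genes with a value in 1 or 2 libraries were not recovered. The recovered library scales equalled median-of-ratios size factors over 12993 genes with reads in every library, up to a constant, with a largest relative difference of 3.8e-10. The deposited FPKM are therefore scaled by size factors (0.58 to 1.54) and not by each library's own total, and FPKM sums range from 499471 to 1052740. Whether a unit counted is a read or a read pair is not given in the sources used here.

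Samples were grouped by sex and dose from the labels, with 5 libraries in each of 8 groups. The labels call the replicates biological, and do not name the animals. Over the 80 pairs of libraries within a group, chi-square per degree of freedom lay between 18.1 and 169, so that no pair agreed within sampling noise.

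Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior and a two-sided test, and an adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. Genes with at least 1 FPKM in at least 5 libraries of the fit were kept. Each dose was compared with the controls of its sex, and a trend over dose rank was fitted, in a fit of the 20 libraries of that sex. The sexes, and the difference between the sexes in the response to a dose, were compared in a fit of all 40 libraries. Shares of reads were compared by exact permutation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for recovery, permutation and plots.

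The comparisons, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule asked for fixed adrenal genes and for called genes with a symbol. Since 0 identifiers matched the 47357 rows of the gene name table (assembly GRCr8), it was applied to identifiers: called genes with a mean of at least 5 FPKM in a compared group. At most 2 of the largest rises and 2 of the largest falls per comparison were named. The fixed rule allowed more per direction, and the lack of names did not force this lower limit. Because no identifier matched, the pathway and cell type lists fixed beforehand were not tested here. Shares of cell types and signs of RNA quality that need gene names were not analysed here. The comparison of all dosed animals of a sex with its controls, the comparison of the sexes within each dose, the tests of the share of reads, the check of sex labels with genes selected from the other libraries, voom on the recovered reads and scaling to library totals were added after seeing the data.

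The tests were run on simulated data: reads were drawn for the real genes from the real means, spreads and library scales, with 200 genes changed by 1.5, 2 or 4-fold in each of 3 simulations. Means and spreads were taken over all libraries of the fit, and genes were drawn independently of each other. For the male 30000x comparison, 92.4% of genes changed 4-fold were found, with 4.7 false calls per simulation among 12939 genes. For the female 30000x comparison these were 82.8% and 6.7 among 13046 genes, and for the sexes in controls 81.8% and 6 among 13718 genes. Alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, library weights, a replicate block, a fit of the compared groups alone, each library left out in turn, voom on the recovered reads and scaling to library totals. Each comparison was also run on 100 splits of its samples, the real one included.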

Results

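RNA was sequenced from adrenal glands of adult male and female Sprague Dawley rats, an outbred laboratory stock, that were controls or had been exposed to a mixture of organophosphate esters (OPEs), chemicals used as flame retardants and plasticizers. The mixture was given at 3 doses, named 30x, 1000x and 30000x in the labels, which do not give the amount behind a multiple. Each of the 8 combinations of sex and dose held 5 libraries, 40 in all, which the labels call biological replicates. Each file listed 32545 genes as FPKM, fragments per kilobase of gene, here scaled by size factors and not by each library's own total. The reads recovered from these values ranged from 13527205 to 23838651 per library, with a median of 17528216. Genes are given by their Ensembl identifiers, because 0 of the identifiers matched the gene name table used here.

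The labels of sex were compared with the genes found in 1 sex. Across all 40 libraries, 5 genes were at 1 FPKM or more in all 20 male libraries and under 0.1 FPKM in all 20 female libraries, and 2 genes showed the opposite. Because these genes were selected on all 40 libraries, they were also selected from the other 39 for each library in turn and then read in the library left out. Each selection held 5 male and 2 female genes, all 40 libraries had each gene of their labelled sex at 1 FPKM or more, and the highest value of a gene of the other sex was 0.095 FPKM. ENSRNOG00000055225 averaged 1020 ± 141 FPKM (SD, n = 5) in female controls and had 0 reads in each male library, at least 448-fold higher in females against a floor of 3 reads per library. This gene's length, as recovered from the values, was 68 bp, which raises its FPKM per read, and it held 847 to 1616 reads per female control library. ENSRNOG00000051257 (988 bp) averaged 50.9 ± 20.5 FPKM (SD, n = 5) in female controls and had 0 reads in each male library, at least 325-fold higher. ENSRNOG00000057231 (3086 bp) averaged 32.9 ± 8.80 FPKM (SD, n = 5) in male controls and had 0 reads in each female library, at least 613-fold higher in males. ENSRNOG00000060048 (1731 bp) averaged 31.2 ± 3.34 FPKM (SD, n = 5) in male controls, and 1 female control library held 3 reads of it while the other 4 held 0. These floors cover counting error only.

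The adrenal glands of control males and control females differed in 728 of 13926 genes tested (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05). Of these, 276 were higher in females (37.9%) and 452 were higher in males. With quantile normalization the split was 378 and 423 (47.2% higher in females), and with scaling to library totals 227 and 455 (33.3%). The median size of the difference was 0.73 on the log2(FPKM + 1) scale, which understates the change of low genes. A difference of at least 1 on this scale was found in 205 genes, 40 higher in females and 165 higher in males. Without any 1 of 3 libraries the count fell by more than 1.5 times: to 460 without male control replicate 1, to 440 without male control replicate 4, and to 336 without female control replicate 3. With library weights the count was 1508, and in a fit of these 10 libraries alone it was 435.

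**Figure D1:**
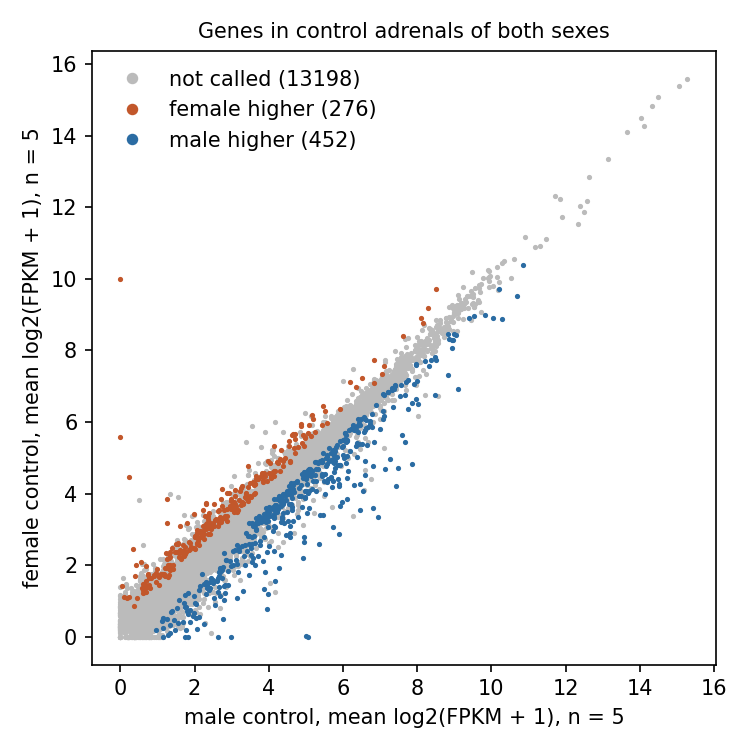
Mean log2(FPKM + 1) of 13926 genes in 5 male control libraries (x axis) and 5 female control libraries (y axis), 1 point per gene. The 276 genes called higher in females lie above the diagonal and the 452 called higher in males below it, and 13198 genes were not called.

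Each dose was compared with the controls of the same sex. In males, 1 of 13110 genes passed the threshold at 30x, and it was lower. ENSRNOG00000029651 (2343 bp) fell from 60.1 ± 4.73 FPKM (SD, n = 5) in male controls to 36.5 ± 1.21 FPKM (SD, n = 5) at 30x. The log2 change was -0.70 (SE 0.10), with a limma adjusted p of 0.0071, and all 5 libraries at 30x lay below the lowest control. The same gene was the only call at 1000x, at 38.7 ± 5.80 FPKM (SD, n = 5), with a log2 change of -0.63 (SE 0.10) and a limma adjusted p of 0.030. At 30000x it averaged 48.7 ± 5.80 FPKM (SD, n = 5), a log2 change of -0.30 (SE 0.10) that did not pass (limma adjusted p = 0.76). These comparisons share the 5 control libraries, so the recurrence of this gene is not independent evidence. The call at 30x was lost with quantile normalization, where the log2 change was -0.66 (SE 0.11, limma adjusted p = 0.119), and with scaling to library totals, where it was also -0.66 (SE 0.11, limma adjusted p = 0.119). The change kept most of its size there while its SE rose. Over all 9 alternatives the adjusted p ran from 0.0051 to 0.119. Leaving out male control replicate 1 gave 3 calls at 30x, and leaving out male 30x replicate 5 gave 2. The call at 1000x was lost when any 1 of the 10 libraries was left out, except male 1000x replicate 3. In those 9 fits the log2 change was -0.66 to -0.58 (limma adjusted p 0.054 to 0.169), about as large as with all libraries, and over the 9 alternatives its adjusted p ran from 0.021 to 0.43.

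In females the same gene averaged 27.7 ± 8.47 FPKM (SD, n = 5) in controls, below male controls (log2 difference -1.15, SE 0.19, limma adjusted p = 2.1e-04). It averaged 36.2 ± 5.58 at 30x, 32.5 ± 6.26 at 1000x and 42.5 ± 15.1 FPKM at 30000x (SD, n = 5 each), and none of these passed the test against female controls. The difference between the sexes in the change at 30x was 1.12 on the log2 scale (SE 0.26), which did not pass the adjustment over all genes (limma adjusted p = 0.21).

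**Figure D2:**
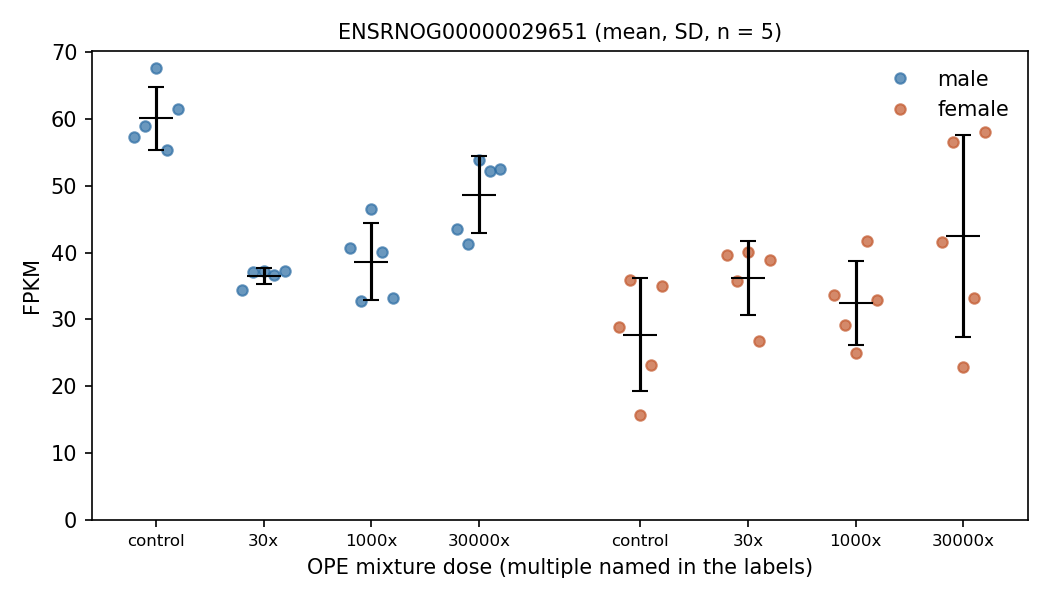
FPKM of ENSRNOG00000029651 in each library by sex and dose, with points for the 5 libraries of a group and a black bar and whiskers for the mean and SD. The 5 male 30x libraries lie between 34.4 and 37.2 FPKM, below the lowest male control at 55.3 FPKM, and with 2 other scalings the log2 change was -0.66 in place of -0.70 and the call was lost.

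At 30000x in males 1 gene passed, and it was higher. ENSRNOG00000055501, with a recovered length of 94 bp, had 0 reads in 4 of 5 male controls and 4 reads in the fifth, against 6 to 18 reads at 30000x. Its level was 5.40 ± 2.18 FPKM (SD, n = 5) at 30000x, 1.45 ± 0.68 at 30x and 1.81 ± 1.20 at 1000x. The log2 change at 30000x was 2.27 (SE 0.34, limma adjusted p = 0.031), and it ran from 2.15 to 4.78 over the alternatives that tested the gene. It was also the only gene with a trend over dose in males, at 0.69 per dose step (SE 0.11, limma adjusted p = 0.047). This slope ran from 0.63 to 1.45 over the other settings that tested the gene, left-out libraries aside. In females the same gene averaged 1.69 ± 1.31 FPKM in controls and 0.90 ± 1.61 FPKM at 30000x (SD, n = 5 each). Its log2 changes there were -0.82 (SE 0.50) at 30x, -0.16 (SE 0.50) at 1000x and -0.63 (SE 0.50) at 30000x, and its trend was -0.12 per dose step (SE 0.16), none of which passed. The difference between the sexes in the change at 30000x was -2.90 (SE 0.63), which did not pass the adjustment over all genes (limma adjusted p = 0.32). Both calls in males rest on a few reads. The change at 30000x missed the threshold with voom on the recovered reads (limma adjusted p = 0.18, with a range from 0.025 to 0.61 over the alternatives that tested it), and leaving out 1 library ended it except for male control replicate 3 and male 30000x replicate 4. In the 8 fits that lost it the log2 change was 2.11 to 2.36 (limma adjusted p 0.060 to 0.169). The trend was kept without male control replicate 3, male 30x replicate 2, male 1000x replicate 3 or male 1000x replicate 5, and was lost without any 1 of the other 16 male libraries, at 0.64 to 0.73 per dose step (limma adjusted p 0.058 to 0.22). It was also lost in 6 of the 7 other settings that tested the gene (limma adjusted p 0.055 to 0.28), and kept with scaling to library totals (limma adjusted p = 0.035).

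In females 0 of 13251 genes passed limma's test at 30x, 0 at 1000x and 0 at 30000x, and 0 had a trend over dose. Genes at an unadjusted p under 0.05 numbered 1053, 221 and 1309 at the 3 doses and 840 for the trend, where independent genes with no effect give 663. Splitting the same libraries at random reached these numbers in 14, 78 and 19 of 100 splits for the doses and 24 of 100 for the trend, the real split included, with 3079, 1849, 2093 and 2607 as the highest of the others. Voom on the recovered reads also called 0 genes in each of these 4 tests. In males the corresponding numbers were 1248, 946 and 771, and 573 for the trend, where independent genes with no effect give 656. Random splits reached them in 16, 22, 36 and 47 of 100, with 1840, 1601, 2454 and 2162 as the highest of the others. The 95% interval of the change on the log2(FPKM + 1) scale lay within ±1 for 90.7%, 91.7% and 91.4% of genes in males at 30x, 1000x and 30000x. In females it did so for 86.1%, 88.9% and 84.1%. This scale understates the change of low genes, so for them an interval within ±1 does not exclude a 2-fold change. On reads simulated from the means and spread of the 20 libraries of a sex, limma found 69.7% of genes changed 2-fold at 30000x in males and 50.7% in females. For genes changed 1.5-fold it found 34.3% and 21.9%. These rates hold for 200 genes changed at once. Genes were drawn independently, with the same spread in every library. Variation shared by genes, or a library that stands apart, is therefore not reproduced in the rates.

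Whether the response to a dose differed between the sexes was tested for each gene as an interaction. At 30x, 1000x and 30000x limma called 0, 0 and 0 of 13926 genes. Genes at an unadjusted p under 0.05 numbered 1828, 651 and 1781, where independent genes with no effect give 696. Random splits reached these numbers in 8, 24 and 6 of 100, with 3488, 2373 and 2704 as the highest of the others, and voom on the recovered reads called 0 genes at each dose. Without female control replicate 1 the count at 30x was 48, without male control replicate 3 it was 1, and without female 30x replicate 2 it was 2. At 30000x it was 1 without female 30000x replicate 1. The replicate block also gave calls at 30x and at 1000x, listed below with the dependence on the processing.

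The 10 most abundant genes took a larger share of the recovered reads in females than in males in every dose group. In controls the share was 25.7 ± 3.10% in females and 20.4 ± 1.64% in males (SD, n = 5 each), with an exact two-sided permutation p of 0.016 and 0.040 after Benjamini-Hochberg adjustment over 10 comparisons. At 30x it was 31.5 ± 4.43% against 20.7 ± 1.81%, at 1000x 28.2 ± 2.54% against 19.05 ± 2.02%, and at 30000x 30.6 ± 5.03% against 19.1 ± 2.83% (SD, n = 5 each). At each of these doses all 5 female libraries lay above all 5 male ones, with an exact permutation p of 0.0079, the smallest this design allows, and an adjusted p of 0.027. No dose differed from the controls of its sex after adjustment. The largest difference was in females at 30x, 5.81 percentage points, with an exact permutation p of 0.048 and an adjusted p of 0.095. Of these 10 genes, ENSRNOG00000034234 (1545 bp) held the most reads, a mean of 7.65% over all libraries. The next was ENSRNOG00000031979 (681 bp) at 2.89%. The 10 genes were not matched to names. How many of them are mitochondrially encoded, which was planned as a sign of RNA quality, was therefore not checked.

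**Figure D3:**
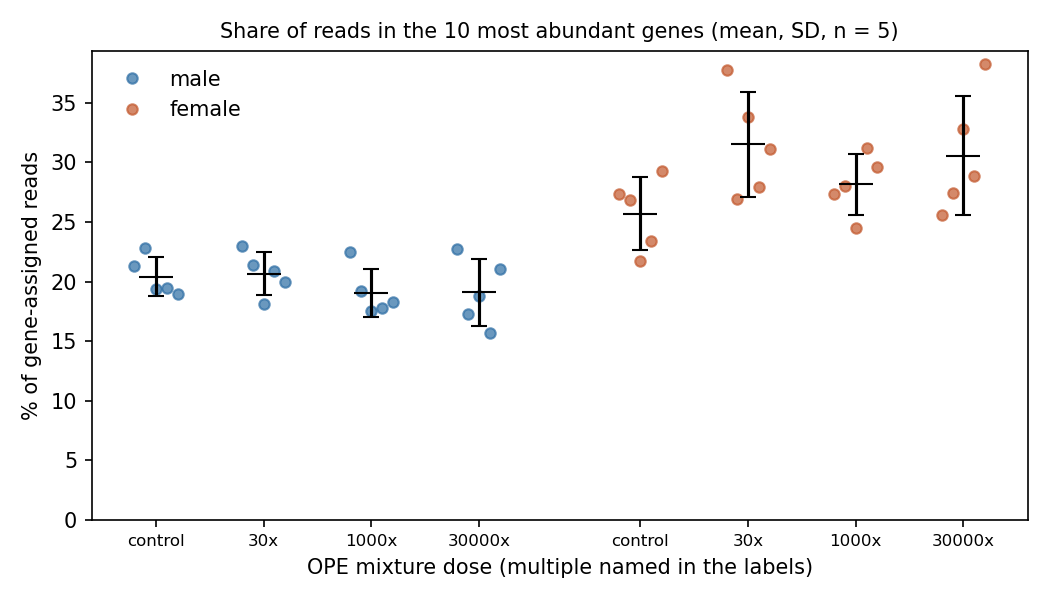
Percent of recovered reads in each library, by sex and dose, in the 10 genes with the highest mean share over all 40 libraries. Points show the 5 libraries of a group, and a black bar and whiskers the mean and SD. Female group means lie between 25.7% and 31.5% and male group means between 19.05% and 20.7%.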

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

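The tests of library depth on the share of reads, of a library of the other sex, of low counts in the gene with the fewest reads, and of dose as the whole cause of on and off genes were chosen after the results were seen. Among 65 groups of 5 values examined, 9 held a value far from the other 4. For independent normal values chance gives about 1 in 20, or 3.2. Where the other 4 values are 0, as for ENSRNOG00000055501 in male controls, any value above 0 is flagged. The count of 9 is therefore no test of an excess over chance.

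The library of female 30000x replicate 5 stood apart in 2 measures: 11905 genes at 1 FPKM or more, against 12390 to 12582 in the other 4 libraries of its group, and a median correlation with its group of 0.908, against 0.958 to 0.959. It also had the highest share of reads in the 10 most abundant genes of all 40 libraries (38.2%, against 25.6% to 32.8% in its group), the fewest genes with reads (14437, against 16576 to 17655) and the lowest size factor (0.58). Low depth is argued against, because after every library was thinned to the same number of reads the lowest of the other 39 libraries was still at 0.946 and this one at 0.908. Uneven loss of long or short transcripts is argued against as well, since the rank correlation over genes between its deviation and gene length was 0.05, within the -0.273 to 0.22 of the other 39. A library of the other sex is argued against, because the 5 genes found only in males among the other 39 libraries were at 0 FPKM in it and the 2 found only in females were at 20.1 FPKM or more. The length trend measures only the uneven loss of long or short transcripts, and poor RNA or a poor library of another form stays open. What also stays open is another makeup of the dissected tissue, which was not tested because it needs gene names. A difference between animals or a response of this animal to the dose stays open as well.

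The larger share of reads in the 10 most abundant genes in females was weighed against depth and transcript length. Among libraries of 15000000 to 20000000 reads, the share was higher in 17 female than in 15 male libraries by 8.48 percentage points (28.3 ± 3.94% against 19.9 ± 2.09%, SD, permutation p = 1e-05, the smallest that 100000 permutations can give), which argues against depth. Without female 30000x replicate 5 the difference between the sexes at 30000x was 9.58 percentage points in place of 11.5, with an adjusted exact permutation p of 0.027 in both cases. Within a sex the relation of the share to the length trend of a library had a Spearman rho of -0.40 in males (permutation p = 0.077, adjusted 0.11; Pearson r -0.50, p = 0.024, adjusted 0.048) and -0.37 in females (permutation p = 0.11, adjusted 0.11; Pearson r -0.31, p = 0.19, adjusted 0.19), 20 libraries each, so that Pearson's r in males alone passed. Without the 2 farthest libraries r was -0.27 and -0.36, and the bound set beforehand for arguing against RNA quality was met by less than the spread of a rho over 20 libraries. That reading was adopted after the values were seen. The length trend of a library was measured against the other libraries of its own group, which share its sex and dose. A difference in RNA quality between the sexes therefore does not enter the length trend. This test cannot decide whether RNA quality contributes to the difference in share between the sexes. Sex remains an untested biological explanation. Handling and the makeup of the dissected tissue were not tested either, because the 10 genes were not matched to names.

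Some genes were on in some animals of a group and off in others: 11 genes in males and 9 in females, 4 of them in both, had a gap of at least 2 on the log2(FPKM + 1) scale with at least 3 libraries on each side and under 1 FPKM below it. Low counts are argued against for 19 of the 20 gene and sex pairs, which had a median of at least 30 reads where on, and over all of them the median was 409. For 1 gene of 54 bp in females the median where on was 9 reads, and low counts stay open there. Dose as the whole cause is argued against too, because 17 of the 20 gene and sex pairs had both on and off animals among the 5 controls. Whether dose adds to it stays open: 2 of the 20 were tied to dose at a permutation p under 0.05, where chance gives 1, and the smallest adjusted p was 0.364. The bound set beforehand against dose, at most 3 of the 20, was met, but counts this small leave a contribution open, a reading adopted after the count was seen. An inherited variant in this outbred stock was not tested, nor were reads shared between near-identical copies.

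The remaining values far from their groups were these. Male 30x replicate 3 held 23838651 reads, against 15169845 to 16888395 in the other 4. Male 1000x replicate 5 had a median correlation with its group of 0.965, against 0.968 to 0.969. ENSRNOG00000029651 was at 34.42 FPKM in male 30x replicate 1, against 36.6 to 37.2. ENSRNOG00000055501 was at 2.262 FPKM in male control replicate 3 and 0 in the other 4 controls, and at 3.717 FPKM in female 30000x replicate 1, against 0 to 0.764. ENSRNOG00000060048 was at 24.013 FPKM in male 1000x replicate 4, against 28.5 to 30.2, and at 0.095 FPKM in female control replicate 3, against 0 in the other 4.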

How the results depend on the processing

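Voom on the recovered reads, scaling to library totals, the comparisons of the sexes within a dose and those of all dosed animals were chosen after the data were seen. The causes of the changes below were not tested. It is known only that fits of 2 groups alone or without a library use fewer samples, and that a stricter filter can leave a gene untested. The pathway and cell type lists, and their alternative with an estimated correlation, were not run, because no identifier could be matched to a gene name.

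The 1 gene called in males at 30x became 0 with quantile normalization and 0 with scaling to library totals. The 1 at 1000x became 0 with quantile normalization, library weights, the 2 groups alone and library totals. The 1 at 30000x became 0 with no filter, library weights, the replicate block, the 2 groups alone and voom. It also became 0 with a mean of at least 5 FPKM, a filter that left this gene untested. The 1 gene with a trend in males became 0 with a pseudocount of 0.1, no filter, quantile normalization, library weights, the replicate block and voom. With a mean of at least 5 FPKM it was again not tested. In females no setting except leaving out a replicate gave a call. For all dosed males the 1 gene became 2 with a pseudocount of 0.1 and 0 with quantile normalization, library weights and library totals.

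Of the 728 genes called between sexes in controls, 704 stayed called with the same sign with library weights (1508 calls), 699 with voom (804 calls), 634 with quantile normalization (801 calls) and 597 with library totals (682 calls). In a fit of the 2 groups alone 435 were called, and 369 of the 704 main calls tested there were kept. The sexes differed at 30x in 511 genes, and in 329 with no filter, 296 with the 2 groups alone and 2323 with library totals. At 1000x they differed in 175, and in 849 with library weights and 630 with library totals. At 30000x they differed in 959, and in 635 with no filter, 1638 with library weights, 81 with the 2 groups alone and 2795 with library totals. With scaling to library totals the median gene lay at -0.209, -0.141 and -0.228 (log2, female against male) at the 3 doses, in place of 0, 0.006 and -0.014. The share of calls higher in females went from 50.3%, 54.3% and 38.8% to 5.6%, 11.7% and 4.3%. The direction split at those doses therefore holds only relative to the scaling used.

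Within a sex the replicate numbers gave no clear pairing of the samples: correlations of same-numbered deviations ran from -0.165 to 0.305 in males and -0.165 to 0.242 in females, and 5 of 20 male and 3 of 20 female libraries correlated best with their own number. Same-numbered pairs averaged 0 in males, as did other pairs, and 0.024 in females against -0.006 for other pairs. Pairing of same-numbered male and female libraries was not examined. The replicate block gave 3 interaction calls at 30x and 1 at 1000x, where 0 were called, and 721 sex calls in controls.

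With each library left out in turn, calls ranged from 1 to 3 in males at 30x, 0 to 1 at 1000x, 0 to 1 at 30000x and 0 to 1 for the trend. In females they ranged from 0 to 1 at each dose and for the trend: 1 at 30x without female 30x replicate 3, 1 at 1000x without female control replicate 5, and 1 at 30000x and for the trend without female control replicate 3. For all dosed animals they ranged from 0 to 2 in males (0 without male control replicate 1 or 2, and 2 without male control replicate 5) and 0 to 1 in females (1 without female control replicate 5). Interactions ranged from 0 to 48 at 30x, 0 to 0 at 1000x and 0 to 1 at 30000x. Sex calls ranged from 336 to 834 in controls, 155 to 953 at 30x, 84 to 169 at 1000x and 343 to 1490 at 30000x. At 30x the count moved by over 1.5 times without male 30x replicates 1 (327), 2 (164), 4 (252) and 5 (307) and female 30x replicates 1 (155), 2 (953) and 5 (205). At 1000x it did so without male 1000x replicates 1 (97) and 3 (99) and female 1000x replicates 1 (90), 2 (84) and 5 (107). At 30000x it did so without male 30000x replicates 2 (601), 3 (400) and 4 (343) and female 30000x replicates 2 (1490) and 5 (620). At the depth of these libraries (13527205 to 23838651 reads) ENSRNOG00000055501 was called on 6 to 18 reads at 30000x, and how far depth limits low genes was not tested.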

Other observations

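The counts of other splits, the comparisons of the sexes within each dose, their separate fits and the comparisons of all dosed animals were chosen after the results were seen. Limma also compared the sexes within each dose, in the same fit of 40 libraries as the controls. It called 511 genes at 30x (257 higher in females, 254 higher in males), 175 at 1000x (95 and 80) and 959 at 30000x (372 and 587), at an adjusted p under 0.05, a split that turned to 130 and 2193, 74 and 556, and 120 and 2675 with scaling to library totals. Of the 276 genes higher in control females, 47 were also called higher in females at 30x, 37 at 1000x and 54 at 30000x, where independent lists share 5.1, 1.9 and 7.4. Of the 452 higher in control males, 60, 55 and 115 were called again, where independent lists share 8.2, 2.6 and 19.1. In all 4 dose groups 17 genes were higher in females and 26 higher in males, no gene was called in opposite directions in any 2 groups, and 76.1% of the control calls had the same sign in all 4. These comparisons use different libraries but share each gene's estimate of spread, so genes of low spread tend to be called in several of them and the values for independent lists are not what no effect would give. With each comparison fitted on its own 10 libraries, 11976 genes were tested in all 4. Of the 157 genes higher in control females in those fits, 87.3%, 97.5% and 81.5% were higher in females at 30x, 1000x and 30000x, against 50.1%, 50.7% and 48% of all genes tested. Of the 265 higher in control males, 87.9%, 98.9% and 90.2% were higher in males, against 49.9%, 49.3% and 52%. Without female 30000x replicate 5, the library that stands apart, 620 genes were called at 30000x.

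The libraries of each comparison were split in other ways. In controls 1 of 100 splits of the 10 libraries, the real one, reached 728 genes, and the highest of the others gave 130. At 30x, 1000x and 30000x the real 511, 175 and 959 genes were each reached by 1 of 100 splits, with 192, 2 and 754 as the highest of the others. A value of 1 of 100 is the smallest that these splits can give, so it argues against chance to that level and does not exclude it. This covers the full sets of libraries only. No splits were run with a library left out or on 2 groups alone, where the counts differ. For the dose comparisons with a call chance was not excluded: in males, 9 of 100 splits reached the 1 gene at 30x (highest other 11), 5 of 100 at 1000x (highest other 53), 8 of 100 at 30000x (highest other 10), 5 of 100 for the trend (highest other 2) and 7 of 100 for all dosed males (highest other 2). Where 0 genes were called, all 100 splits reach that count by construction, which says nothing of chance. This holds for females at 30x, 1000x and 30000x (highest other 332, 1 and 62), the female trend (9), all dosed females (2) and the interactions at 30x, 1000x and 30000x (1040, 1 and 135). There the numbers of genes at an unadjusted p under 0.05, given with the comparisons (992 for all dosed females), were each reached by at least 6 of 100 splits. The median of the other splits was 0 calls in each of these comparisons, and what sets apart the few splits with many calls was not tested.

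A hypothesis of a dose response common to both sexes was tested from the log2 changes of 12822 genes, which come from different libraries in males and females. The correlation across genes, which are not independent replicates, was -0.272 at 30x, -0.181 at 1000x and -0.214 at 30000x, against ranges of -0.291 to 0.279, -0.283 to 0.364 and -0.216 to 0.392 in 99 random relabellings. A common response was to show as a real value among the highest 5 of 100, and the real value was reached by 98, 98 and 99 of 100, the real one included, so this test gave no sign of one. The lower side was looked at only after the negative sign was seen: 3, 3 and 2 of 100 were as low, and 4, 8 and 5 of 100 were as far from 0. The bound set beforehand against a common response, a value within the relabellings, was met, but how large a response the test would have found was not measured, so a small one stays open. The 3 doses share the 5 controls of each sex, so these are not independent results.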
